A study of Mus musculus with 8 samples.

How the data were processed

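RNA was measured in 8 whole-cornea libraries of male mice, 4 GRflox and 4 corneaGRKO, each from a pool of 4 to 6 corneas on a C57BL/6J/FVB background. Libraries were read as 75 nt pairs, per the labels. Groups and replicate numbers came from the sample titles. The libraries are separate pools, so p-values measure the spread between pools. The control mice lacked Cre, so effects of Cre and of receptor loss are not separated by the design.

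The table holds log2 normalized expression values that the authors deposited, for 24918 entries named by symbol, Entrez gene and locus. Bowtie2, HTSeq and DESeq2 were used by the authors, per the submitters' processing notes, with versions not given in the sources used here. The genome build is mm9 in the processing notes and the series design and mm10 in the extraction protocol of the labels, so no coordinates are printed. The transformation behind the log2 values is not stated. The median SD of GRflox libraries was 0.0144 at mean values of 2 to 3 and 0.0674 at 10 to 12, so differences of weakly expressed genes may be compressed. Fold sizes in the report are differences on the deposited scale. A total of 5382 entries were exactly 0 in every library. More than 40000000 reads per sample were aligned, per the labels, but the depth of each library is not known and whole reads could not be recovered, so no interval for counting error is given. Entrez genes were looked up in the RefSeq gene table of GRCm38.p6 for chromosomes only, and 99.6% of entries matched. The table held 0 value columns beyond those of the 8 libraries.

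Entries with a mean log2 value of at least 5 (13269) were tested with limma 3.58.1 in R 4.3.3, using a mean-variance trend, group as the only term and Benjamini-Hochberg adjustment, two-sided. Positive differences mean higher in corneaGRKO. Of 1228 entries of genes counted at more than 1 locus, 12 were tested and 0 passed the threshold. Lists of marker and pathway genes (34) were fixed before the data were examined, and the 28 with at least 3 tested genes were tested with camera at a preset correlation of 0.01. Camera called 15 of them, all higher, and 0 of these calls held with an estimated correlation, where the smallest adjusted p was 0.198. Fry, which asks whether a list's genes move on balance and not whether they move more than other genes, called 2. Genes are named by a rule fixed beforehand: Nr3c1 and Pax6, the 10 largest differences in each direction among genes past the threshold with separated groups (leaving out unnamed gene models, genes of the Y chromosome and Xist), and the 3 genes of each list with the smallest adjusted p. Cx3cr1, Isg15, Stat2, Krt4, Krt7, Krt12, Krt18, Agr2, Nfkbia, Anxa1, Il1r2, Fmod, Ogn, B2m, Nlrc5, Tap1, Asns, Slc7a3, Atf5, Sesn2, Slc7a5, Mthfd2, Mgp and Comp fall outside this rule and were chosen after their values were seen. Some genes that the rule takes in are not reported here.

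The test was tested on simulated data built on the means and spreads of the 13269 genes, with 200 genes changed. For the comparison of corneaGRKO with GRflox it called 64.2% of genes changed by 0.25 on the log2 scale and 100% of those changed by 0.5 or by 1, and 5.88% of its calls were unchanged genes. In that simulation genes were independent, unlike in tissue. No pair of libraries was a duplicate, since the smallest median absolute difference between 2 libraries was 0.0427. The same replicate numbers occur in both groups, and a check of whether they pair the libraries is given with the alternatives.

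The 19 alternatives listed before the data were examined were the replicate number as a block, no filter, a stricter filter at a mean of 7, quantile normalization, median centring, a pseudocount of 16 on the linear scale, limma without the trend, with library weights and with robust moderation, each library left out in turn, camera with an estimated correlation, and fry. A further 3 were added after the data were seen: leaving out corneaGRKO replicates 1 and 4 together, removing a trend on GC content and transcript length from each library (natural splines with 5 degrees of freedom each, transcripts of GENCODE for GRCm38), and the first component of the within-group deviations as a covariate. Another 3 lists (MHC class I and immunoproteasome, amino-acid response, limbal and scleral rim stroma) were also added after the data were seen. Count models were not run, as the values are not counts.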

Results

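Whole corneas of male mice aged 3 months were profiled by RNA sequencing. Mice of the corneaGRKO line carried a floxed glucocorticoid receptor gene together with Cre under the Pax6 P0 promoter, so that the receptor is deleted in the corneal epithelium. Their GRflox littermates carried the floxed gene without Cre. Each group had 4 libraries, numbered 1, 3, 4 and 5, and each library came from a pool of 4 to 6 corneas. The comparison of the groups asks how loss of the receptor in the corneal epithelium changes the cornea, with its development, inflammation and blood vessels named in the study's title. The labels give more than 40000000 reads per sample, and the depth of each single library is not known, because the table used here holds log2 normalized values.

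Nr3c1, which encodes the glucocorticoid receptor (Entrez gene 14815, chromosome 18), fell by 0.47 on the log2 scale in corneaGRKO corneas (SE 0.064, n = 4 per group, limma adjusted p = 0.00767), from a mean of 11.22 ± 0.114 (SD) to 10.75 ± 0.0963. The 4 GRflox libraries had values of 11.07, 11.21, 11.28 and 11.34, and the 4 corneaGRKO libraries had values of 10.61, 10.78, 10.83 and 10.78. All 4 corneaGRKO libraries thus lay below all 4 GRflox libraries. Whole cornea also holds stroma and endothelium, in which Cre was not aimed at the gene, and values per gene do not separate the floxed exons from the rest of the transcript. Pax6, a transcription factor of eye development whose promoter drove Cre, did not pass the test (log2 difference -0.01, SE 0.0476, limma adjusted p = 0.935).

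Oas2, Slfn4, Ifit1, Ifi44 and Myoc had the largest increases among genes past the threshold. Oas2, an activator of antiviral RNA decay, rose by 1.41 (SE 0.199) on the log2 scale, and Ifit1, which binds viral RNA, rose by 1.19 (SE 0.138). Ifi44 rose by 1.15, Slfn4 by 1.21, Zbp1, a sensor of Z-form nucleic acid, by 0.98, and Rtp4 by 0.87. Myoc, a secreted glycoprotein of the anterior eye, rose by 1.08, Serpine2, a protease inhibitor, by 0.93, and Tnfsf10, which encodes the death ligand TRAIL, by 0.87. Myoc, Serpine2 and Tnfsf10 were highest in corneaGRKO replicate 4 (11.77, 10.46 and 9.60), the library that also held the highest photoreceptor values. Oas2, Slfn4, Ifit1, Ifi44, Zbp1 and Rtp4 were lowest in that library among the corneaGRKO libraries. The largest decreases were smaller: Enpep, an aminopeptidase, fell by 0.62, Stfa1, a stefin protease inhibitor, fell by 0.51, the clock gene Arntl fell by 0.51, and the cytochrome P450 gene Cyp2b19 fell by 0.49. Eva1a fell by 0.49, Adrb3, a beta-adrenergic receptor, fell by 0.46, the epithelial protease Tmprss11d fell by 0.45 and Nyap1 fell by 0.43. The call of Myoc was lost without GRflox replicate 1 (limma adjusted p = 0.0558), GRflox replicate 5 (0.0682) or corneaGRKO replicate 3 (0.0711), and that of Serpine2 without the same libraries (0.0518, 0.0682 and 0.0623). Rtp4 missed the threshold without GRflox replicate 3 (0.0658), GRflox replicate 5 (0.077), corneaGRKO replicate 3 (0.0849) or corneaGRKO replicate 5 (0.0557). Eva1a missed it without GRflox replicate 1 (0.0518) or corneaGRKO replicate 3 (0.0623), and Tnfsf10 without GRflox replicate 5 (0.0512). Stfa1, Oas2, Slfn4 and Cyp2b19 belong to families of similar genes, so their values are uncertain where reads could have been shared.

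Of 13269 genes tested, 245 passed a limma adjusted p of 0.05 (n = 4 per group), 176 of them higher and 69 lower in corneaGRKO. Only 5 of the 245, Oas2, Slfn4, Ifit1, Ifi44 and Myoc, differed by at least 1 on the log2 scale, all of them higher. The median log2 difference was 0.39 among the higher genes and -0.28 among the lower ones. In all 245 the groups did not overlap, which the selection by this test with 4 per group makes likely. Over all tested genes the share was 10.5%, against an average of 2.86% under random labels. Genes move together, so these shares do not by themselves show an effect of genotype. The number of genes depended on which library was left out. It was 68 without GRflox replicate 5, 83 without corneaGRKO replicate 3, 95 without GRflox replicate 1 and 114 without GRflox replicate 3. It was 137 without corneaGRKO replicate 5 and 574 without corneaGRKO replicate 1. Without GRflox replicate 4 it was 228, and without corneaGRKO replicate 4 it was 248, 203 of them higher. With library weights 1980 genes passed, 973 of them higher, so that fit showed no excess of higher over lower genes. The weights were estimated from the same 8 libraries and ran from 0.334 (GRflox replicate 4) to 2.25 (GRflox replicate 3). The p-values with weights, here and below, may therefore be too small. Among the 1980 were 44 named genes that otherwise did not pass. With the replicate number as a block 663 genes passed, 466 of them higher, and the named genes among them are given in the part on processing. A division of the 8 libraries that does not follow genotype gave 2338 genes.

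**Figure D1:**
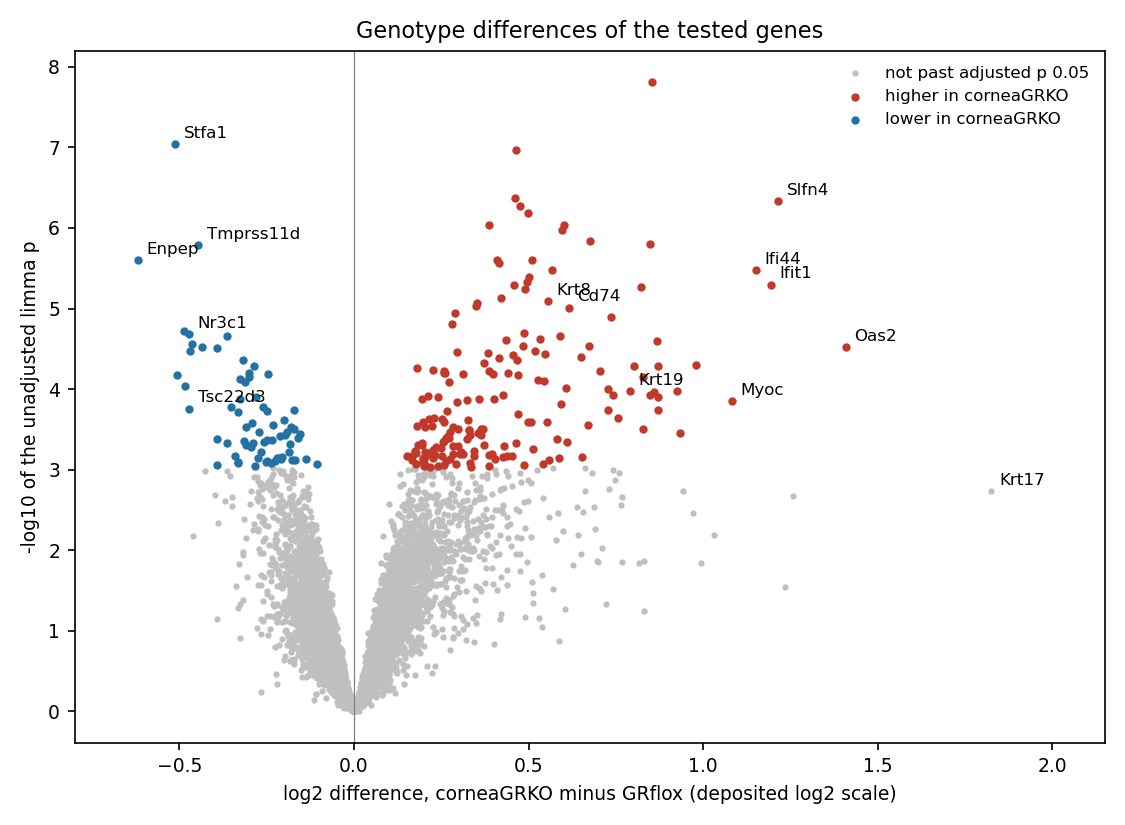
Each point is 1 of the 13269 tested genes, with the log2 difference between corneaGRKO and GRflox on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. The 176 higher (red) and 69 lower (blue) genes past an adjusted p of 0.05 are coloured, and Krt17, in grey, had the difference of 1.82 without passing.

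All 19 genes of the interferon-response list were higher in corneaGRKO, and 13 of them rose past the threshold over all genes, while all 19 passed when adjusted over the list alone. Ifit3 rose by 0.85 (SE 0.0863), Oasl2 by 0.57, Isg15, a ubiquitin-like antiviral protein, by 0.85, and the signal transducer Stat2 by 0.40. The median log2 difference of the list was 0.55, and camera in limma called it higher (adjusted p = 1.01e-24). That call was lost with an estimated correlation (adjusted p = 0.198), while fry gave an adjusted p of 0.00833. The list mean stood 0.65, 0.59, 0.40 and 0.69 above the GRflox mean in corneaGRKO replicates 1, 3, 4 and 5. The number past the threshold was 5 without corneaGRKO replicate 3, 6 without GRflox replicate 5 and 7 without GRflox replicate 3. It was 9 without corneaGRKO replicate 5, 11 without GRflox replicate 1 and 13 without GRflox replicate 4 or corneaGRKO replicate 1. Without corneaGRKO replicate 4 it was 15, and without corneaGRKO replicates 1 and 4 together 14. Isg15 missed the threshold without corneaGRKO replicate 3 (adjusted p = 0.0643), GRflox replicate 5 (0.0584) or GRflox replicate 3 (0.052), and Stat2 without corneaGRKO replicate 3 (0.0513) or GRflox replicate 5 (0.0519).

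Some antigen-presenting, macrophage and complement genes were also higher. Cd74, the invariant chain of MHC class II, rose by 0.61 (SE 0.0764), and the class II chains H2-Aa and H2-Ab1 rose by 0.47 and 0.43, so that 3 of 7 tested antigen presentation and dendritic cell markers rose (6 when adjusted over the list alone). Camera called this list higher (adjusted p = 8.01e-07), a call lost with an estimated correlation (adjusted p = 0.265), and fry gave an adjusted p of 0.0296. Of 13 macrophage and monocyte markers, 4 rose (10 when adjusted over the list alone): Ptprc by 0.34, Csf1r, the receptor of macrophage colony-stimulating factor, by 0.40, the mannose receptor Mrc1 by 0.44 and Cx3cr1 by 0.26. Camera gave this list an adjusted p of 6.57e-09, and 0.265 was the adjusted p with an estimated correlation. Among 12 complement genes, 3 rose (9 when adjusted over the list alone), among them C4b by 0.73 and C2 by 0.31, with a camera adjusted p of 4.23e-08 and an adjusted p = 0.265 with an estimated correlation. C4b and C2 lie on chromosome 17, as do H2-Aa and H2-Ab1, and changes local to a linked region were not tested for these lists. In corneaGRKO replicate 4 the antigen presentation, macrophage and complement list means were at their highest (0.48, 0.42 and 0.54), and that library also held the highest photoreceptor values. Without corneaGRKO replicate 4 alone, 3 antigen presentation, 3 macrophage and 3 complement genes were past the threshold. Without corneaGRKO replicates 1 and 4 together, the counts were 3, 5 and 4. These counts cannot exclude neighbouring tissue, because the conjunctival (0.45 and 0.38) and pigment (0.22 and 0.15) list means were also raised in corneaGRKO replicates 3 and 5. Without GRflox replicate 5, the macrophage and complement counts were both 0 and the antigen presentation count was 2, and quantile normalization left 0 macrophage markers past the threshold. Each of the 4 macrophage calls was lost without GRflox replicate 1 (limma adjusted p from 0.123 to 0.138), GRflox replicate 3 (0.0865 to 0.113), GRflox replicate 5 (0.134 to 0.153), corneaGRKO replicate 3 (0.134 to 0.152) or corneaGRKO replicate 5 (0.0742 to 0.0898). Those of Csf1r (0.0585) and Mrc1 (0.0578) were lost without GRflox replicate 4, and those of Ptprc (0.0626) and Cx3cr1 (0.0783) without corneaGRKO replicate 4. H2-Ab1 and C2 were lost without GRflox replicate 1 (0.077 and 0.106), 3 (0.102 and 0.0912), 4 (0.0696 and 0.065) or 5 (0.13 and 0.144) and without corneaGRKO replicate 3 (both 0.134) or 5 (0.0831 and 0.0557). C4b was lost without GRflox replicate 1 (0.0558), GRflox replicate 5 (0.064) or corneaGRKO replicate 3 (0.0623).

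The keratin genes Krt19, Krt8 and Krt13 rose. Krt19 rose by 0.79 (SE 0.129), Krt8 by 0.56 (SE 0.0675) and Krt13 by 0.54 (SE 0.116), so that 3 of 7 tested conjunctival and goblet cell markers rose (5 when adjusted over the list alone), with limma adjusted p from 0.00398 to 0.0483. Krt4 (1.03, adjusted p = 0.122), Krt7 (0.71, adjusted p = 0.144) and Krt18, the partner of Krt8 in keratin filaments (0.06, adjusted p = 0.621), did not pass over all genes. The list's median log2 difference was 0.56, and camera called it higher (adjusted p = 7.89e-06), a call lost with an estimated correlation (adjusted p = 0.265). Agr2, a goblet cell gene, had a difference of 0.02 (-0.00359 with quantile normalization) and did not pass. Krt17, a keratin of stressed and appendage epithelium, had the largest difference of any gene named here, 1.82, but its 4 corneaGRKO values of 10.74, 11.08, 13.25 and 11.46 were widely spread (SE 0.438, limma adjusted p = 0.0701), and it passed without corneaGRKO replicate 1 (0.0268) or 4 (0.00356). The 12 tested epidermal keratinization genes, among them Sprr1a (0.83) and Sbsn (0.20), held 0 past the threshold and 1 when adjusted over the list alone, and the list missed camera's threshold (adjusted p = 0.0765) but passed it without GRflox replicate 1 (0.0407), GRflox replicate 3 (0.042), corneaGRKO replicate 3 (0.0445) or corneaGRKO replicate 4 (0.0144). Of the 19 corneal epithelium markers, 0 passed the limma test, either over all genes or adjusted over the list alone. Krt15 was 0.77 (adjusted p = 0.0829, but 0.0331 and 0.0385 without corneaGRKO replicate 1 or 4), Krt14 0.48 and Clu 0.21 (adjusted p = 0.0401 without corneaGRKO replicate 1), while Krt12, the main keratin of the corneal epithelium, had a difference of -0.18 (adjusted p = 0.545). This list's median was -0.06 and its mean 0.00397, and camera put it lower (adjusted p = 0.865). The conjunctival list mean was 0.35, 0.45, 0.94 and 0.38 above the GRflox mean in corneaGRKO replicates 1, 3, 4 and 5. Replicate 4 also had the highest retina and pigment list means (1.63 and 0.53). With the pigment list as a covariate, taken up below, the conjunctival median was 0.0944 and 0 genes passed. Without corneaGRKO replicates 1 and 4 together Krt13 (adjusted p = 0.0934) no longer passed and Krt7 (0.00341) did. Krt19 missed the threshold without GRflox replicate 1 (0.0518), GRflox replicate 5 (0.0685) or corneaGRKO replicate 3 (0.0513). Krt13 missed it without GRflox replicate 1 (0.133), 4 (0.0731) or 5 (0.155), without corneaGRKO replicate 3 (0.128), 4 (0.0521) or 5 (0.0723) and with quantile normalization (0.0528), the pseudocount (0.0502) or no trend (0.0502). Krt7 passed without corneaGRKO replicate 4 (0.00824). With library weights Krt4 (0.0443), Krt7 (0.0278), Krt15 (0.0263), Krt17 (0.0123), Clu (0.0263) and Sbsn (0.0417) passed.

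**Figure D2:**
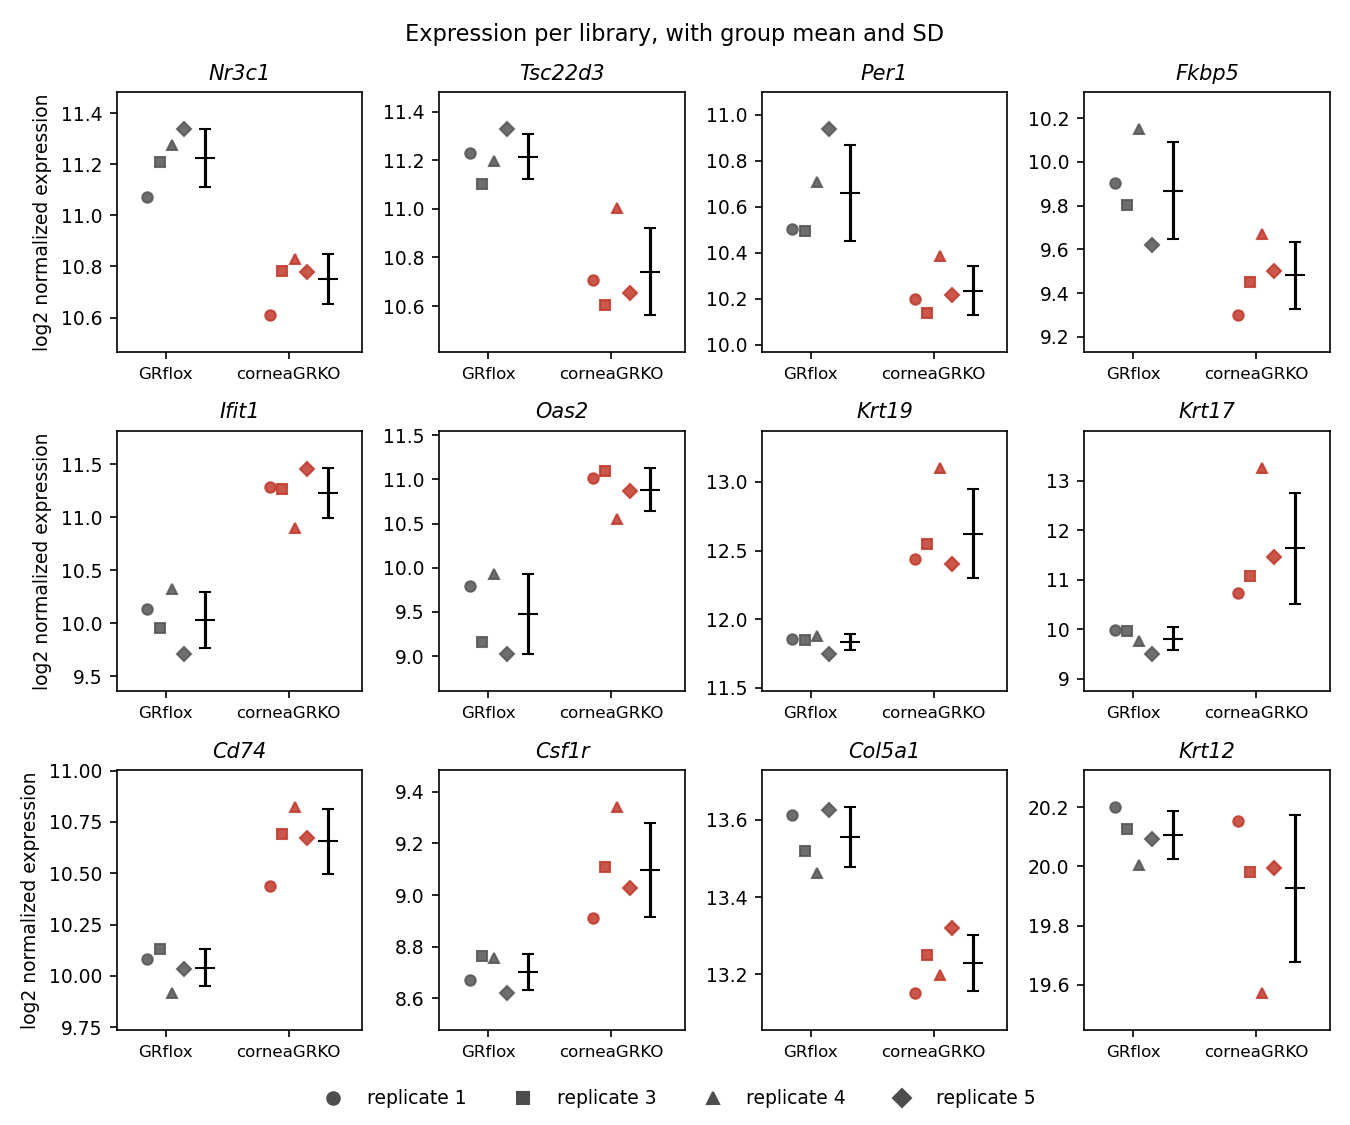
Points are the log2 normalized values of 12 genes in each of the 8 libraries, with a marker shape for each replicate number, and bars are the group mean and SD (n = 4). The vertical axes differ and do not start at 0. The corneaGRKO values of Nr3c1 all lie below the GRflox values, while Krt17 ranges from 10.74 to 13.25 in corneaGRKO.

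Of 19 tested glucocorticoid-responsive genes, 1 passed the threshold over all genes. Tsc22d3, which encodes the anti-inflammatory protein GILZ and is induced by glucocorticoids, fell by 0.47 (SE 0.0823, limma adjusted p = 0.0217). The clock gene Per1 had a difference of -0.43 (adjusted p = 0.0515) and the chaperone gene Fkbp5 of -0.39 (adjusted p = 0.105). Adjusted over the list alone, 4 genes passed as lower (Tsc22d3, Per1, Fkbp5 and Nfkbia) and 2 as higher (Anxa1 and Il1r2). The list's median was -0.03, and camera did not call it (adjusted p = 0.568). Per1 passed with the replicate number as a block (adjusted p = 0.0188), without corneaGRKO replicate 4 (0.0375), with robust moderation (0.0499), with library weights (0.0154) and with the GC and length trend removed (0.044). Fkbp5 passed with the replicate block (0.0275) and with library weights (0.017), Nfkbia without GRflox replicate 4 (0.0253) and with library weights (0.0144), and Anxa1 with library weights (0.0448). Tsc22d3 missed the threshold without GRflox replicate 1 (adjusted p = 0.0731), GRflox replicate 5 (0.0835), corneaGRKO replicate 3 (0.078) or corneaGRKO replicate 5 (0.0611). Of 3 tested genes of steroid receptors and steroid-converting enzymes, Nr3c1 alone passed over all genes and adjusted over the list alone, with Nr3c2 at 0.07 and Esr1 at 0.06. That list had a positive median (0.06) and a negative mean (-0.11), and camera put it lower (adjusted p = 0.568).

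The stromal matrix genes Col5a1, Col6a2 and Kera fell. The collagen gene Col5a1 fell by 0.33 (SE 0.0512), Col6a2 fell by 0.23 (SE 0.0428) and Kera, which encodes the corneal proteoglycan keratocan, fell by 0.29 (SE 0.057), 3 of 17 stromal keratocyte markers, with limma adjusted p from 0.0127 to 0.0369. Adjusted over the list alone, 6 were lower and 4 were higher, the latter including the small proteoglycan gene Fmod (0.74) and Ogn (0.38). The list's median was -0.09 and its mean 0.02, and camera did not call it (adjusted p = 0.175), except without corneaGRKO replicate 4 (0.0396). The 3 calls went to 0 without GRflox replicate 1 (limma adjusted p from 0.0509 to 0.111), GRflox replicate 5 (0.0572 to 0.12), corneaGRKO replicate 3 (0.0502 to 0.132), or corneaGRKO replicates 1 and 4 together (0.0547 to 0.0969). Col6a2 was also lost without GRflox replicate 3 (0.0612) or corneaGRKO replicate 5 (0.0586) and with quantile normalization (0.0541). Kera was lost without GRflox replicate 3 (0.0949) or corneaGRKO replicate 4 (0.0534). Fmod passed without corneaGRKO replicate 1 (0.012) or 4 (0.0255), with median centring (0.0458) and with the GC and length trend removed (0.044), and Ogn without corneaGRKO replicate 1 (0.0483). Of 16 fibrosis and matrix remodelling genes, the matrix protease Mmp3 rose by 0.83 (SE 0.129) and Spp1, which encodes osteopontin, by 0.44 (SE 0.0679), 5 genes passed when adjusted over the list alone, and Tnc stood at 0.42 (adjusted p = 0.068, but 0.024 without corneaGRKO replicate 1). Mmp3 missed the threshold without GRflox replicate 5 (adjusted p = 0.0544). Camera called the list higher (adjusted p = 0.0182), a call lost with an estimated correlation (adjusted p = 0.435) and without corneaGRKO replicate 3 (0.0666). Its mean was 0.04, 0.23, 0.29 and 0.05 in corneaGRKO replicates 1, 3, 4 and 5, against up to 0.05 in GRflox, and replicate 4 also held the highest photoreceptor values. With library weights Fmod (0.00326), Ogn (0.0123) and Tnc (0.0122) passed.

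No vessel marker passed the threshold over all genes with group as the only term. With the replicate number as a block, Flt1, Emcn, Vwf, Mmrn1, Lyve1, Reln, Rgs5 and Myh11 passed, with their values in the part on processing. Camera's calls of the blood endothelium, lymphatic and pericyte lists as higher were lost with an estimated correlation (adjusted p = 0.432, 0.265 and 0.395). Of 17 blood endothelium markers, 16 had positive differences, with Flt1, a receptor of VEGF, at 0.57 (limma adjusted p = 0.0504), Emcn at 0.18 and Vwf at 0.23, and 2 passed when adjusted over the list alone. Camera gave the list an adjusted p of 6.64e-05 (adjusted p = 0.432 with an estimated correlation), a call also lost with fry (adjusted p = 0.186) and at a mean of at least 7 (0.185). The list mean was 0.03, 0.24, 0.21 and 0.05 above the GRflox mean in corneaGRKO replicates 1, 3, 4 and 5, against up to 0.04 in a GRflox library. Flt1 passed without corneaGRKO replicate 1 (adjusted p = 0.0272) or 4 (0.00115), with median centring (0.0425), with library weights (0.00917) and with the GC and length trend removed (0.045). Emcn passed without corneaGRKO replicate 1 (0.0484) and with library weights (0.0359). The 6 lymphatic endothelium markers, with Mmrn1 at 0.50, Lyve1 at 0.36 and Reln at 0.35, had a camera adjusted p of 0.00013 and an adjusted p = 0.265 with an estimated correlation, and 4 passed when adjusted over the list alone. Mmrn1 (0.0181) and Lyve1 (0.0322) passed over all genes without corneaGRKO replicate 1, and Mmrn1 with the GC and length trend removed (0.0443). With library weights Mmrn1 (0.00609), Lyve1 (0.00975) and Reln (0.0448) passed, as did the pericyte markers Anpep (0.0395) and Myh11 (0.0384). The 7 pericyte and mural cell markers, with Anpep at 0.37, Rgs5 at 0.27 and Myh11 at 0.23, had 3 passing when adjusted over the list alone (camera adjusted p = 0.016, adjusted p = 0.395 with an estimated correlation). The lymphatic and pericyte list means were highest in corneaGRKO replicate 4 (0.48 and 0.35), which also held the highest photoreceptor values, and the pericyte mean was -0.00220 in corneaGRKO replicate 1. Among 16 angiogenic and antiangiogenic factors, Col18a1 was at 0.45, Angpt1 at 0.35 and Fgf1 at -0.15, and 0 passed when adjusted over the list alone (camera adjusted p = 0.0182, adjusted p = 0.435 with an estimated correlation, and 0.0565 without corneaGRKO replicate 3). Angpt1 passed without corneaGRKO replicate 1 (0.0272) and Col18a1 without corneaGRKO replicate 4 (0.0452), and both with library weights (0.0177 and 0.0212). The mean of this list was 0.00859, 0.14, 0.25 and 0.07 in corneaGRKO replicates 1, 3, 4 and 5, against up to 0.05 in GRflox.

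Of 12 tested cytokine, chemokine and acute-phase genes, 10 had positive differences and 0 passed limma's threshold over all genes or adjusted over the list alone, with Il33 at 0.70 (adjusted p = 0.168), Tslp at 0.19 and Tnf at -0.14. Camera called the list higher (adjusted p = 0.0182), a call lost with an estimated correlation (adjusted p = 0.435), with fry (adjusted p = 0.274), with library weights (0.106) and without GRflox replicate 5 (0.123). Il33 passed without corneaGRKO replicates 1 and 4 together (0.0184) and with library weights (0.0406), as did Tslp with library weights (0.0236). The list mean was 0.00635, 0.09, 0.40 and 0.15 in corneaGRKO replicates 1, 3, 4 and 5, against up to 0.11 in GRflox. Replicate 4 also held the highest photoreceptor values. The 17 innate sensing and NF-kB genes, with Tlr3 at 0.24, Tlr2 at 0.19 and Tlr1 at 0.15, likewise held 0 past the threshold in either count, with a camera adjusted p of 0.0122, an adjusted p = 0.301 with an estimated correlation and one of 0.0548 at a mean of at least 7. Tlr3 passed without GRflox replicate 4 (0.0428) or corneaGRKO replicate 1 (0.0374) and with library weights (0.0052), as did Tlr1 with library weights (0.0392). This list's mean was -0.02, 0.07, 0.13 and 0.08 in corneaGRKO replicates 1, 3, 4 and 5, against up to 0.02 in GRflox. The 2 tested neutrophil markers were Ltf (0.54, adjusted p = 0.378) and Csf3r (0.08), the 2 tested mast cell markers were Cpa3 (0.14) and Kit (0.03), and 0 of 17 lymphocyte markers reached the level needed for a test.

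Among retina, pigment cell and nerve markers 1 gene, Tyrp1, passed the threshold over all genes, and camera's calls of these lists as higher were lost with an estimated correlation (adjusted p = 0.435, 0.265 and 0.265). Of 5 tested retina markers, all had positive differences and 0 passed limma's threshold over all genes or adjusted over the list alone, with Gnat1, a photoreceptor G protein, at 0.83 (adjusted p = 0.319) and Prph2 at 0.53. Gnat1 stood at 6.69, 6.16, 8.21 and 6.01 in corneaGRKO replicates 1, 3, 4 and 5, against 5.84 to 6.02 in GRflox. Camera called the retina list higher (adjusted p = 0.0182, adjusted p = 0.435 with an estimated correlation), a call also lost without GRflox replicate 4 (0.096) or corneaGRKO replicate 1 (0.0609) and with library weights (0.358). Of 5 pigment cell and iris markers, Tyrp1, an enzyme of melanin synthesis, rose by 0.56 (SE 0.118, limma adjusted p = 0.0451), and Dct (0.48) and Mlana (0.15) did not pass over all genes, while all 5 passed when adjusted over the list alone (camera adjusted p = 8.65e-05, adjusted p = 0.265 with an estimated correlation). Tyrp1 missed the threshold without GRflox replicate 1 (0.109), 3 (0.12), 4 (0.0592) or 5 (0.145), without corneaGRKO replicate 1 (0.0509) or 3 (0.083) and with quantile normalization (0.0526). Dct passed without corneaGRKO replicate 4 (0.0458) or 5 (0.0425) with median centring (0.0491) and with library weights (0.0249). The 8 nerve and Schwann cell markers, with S100b at 0.24 and Sox10 at 0.20, had 4 passing when adjusted over the list alone (camera adjusted p = 0.000792, adjusted p = 0.265 with an estimated correlation, and 0.051 at a mean of at least 7), and S100b passed over all genes without corneaGRKO replicate 5 (0.0478) and, like Sox10, with library weights (0.0274 and 0.0284). The pigment and nerve list means were highest in corneaGRKO replicate 4 (0.53 and 0.22), as were the photoreceptor values. The 13 lens markers, with Crygd at -0.17, Bfsp1 at -0.20 and Crygc at -0.18, were not called (camera adjusted p = 0.37, 0 when adjusted over the list alone), except without corneaGRKO replicate 5 (camera adjusted p = 0.00352).

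**Figure D3:**
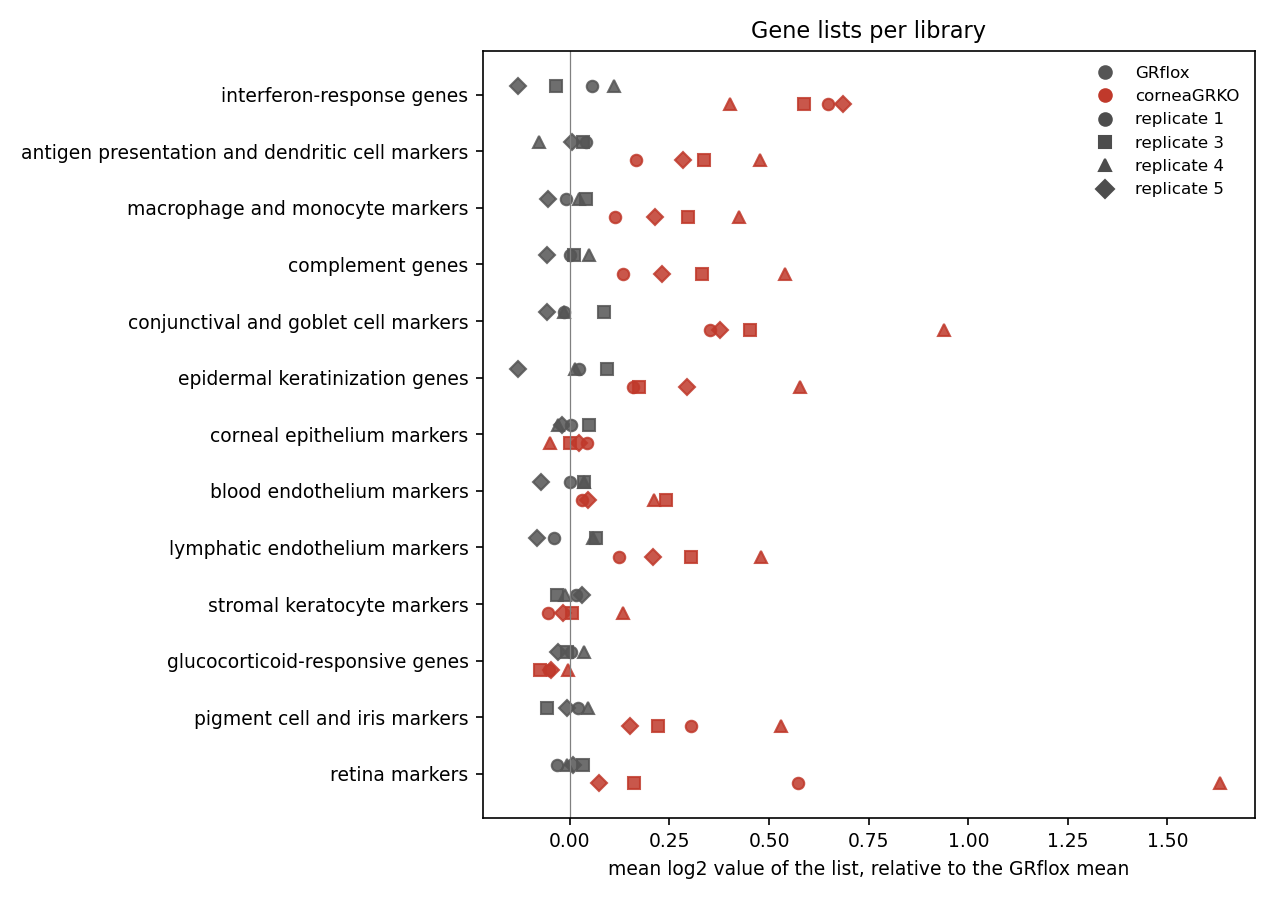
Points are the mean log2 value of the tested genes of 13 lists in each library, relative to the GRflox mean on the horizontal axis, with a marker shape for each replicate number. The interferon-response mean is lowest in corneaGRKO replicate 4 (0.40) among the corneaGRKO libraries, where the retina mean is highest (1.63).

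The remaining lists held few calls. Of 18 proliferation genes, Ccnb2, a cyclin of mitosis, fell by 0.24 (SE 0.0510, limma adjusted p = 0.0476), with Aurka at -0.18 and Cdc20 at -0.22, and 1 gene passed when adjusted over the list alone (camera adjusted p = 0.0964, 0.0368 without GRflox replicate 5 and 0.026 without corneaGRKO replicate 4). The list was mixed, with a median of -0.07 and positive differences in 7 of the 18 genes. Ccnb2 missed the threshold without GRflox replicate 1 (0.123), 3 (0.0718), 4 (0.0704) or 5 (0.073), without corneaGRKO replicate 3 (0.128), 4 (0.0771) or 5 (0.111), with no filter (0.0529) and with the pseudocount (0.0502). Of 16 circadian clock genes, Arntl alone fell (limma adjusted p = 0.0116), with Per2 at 0.32 and Nr1d1 at -0.17, and adjusted over the list alone 1 was lower and 1 higher. The clock list's median was 0.03 and its mean -0.00290, and camera put it higher (adjusted p = 0.985). The 9 corneal endothelium markers (Slc4a11 -0.26, Slc4a4 -0.13, Aqp1 -0.15, camera adjusted p = 0.0981, 1 lower when adjusted over the list alone) and the 18 epithelial junction genes (Dsg1a -0.22, Dsg3 0.14, Cldn1 0.31; camera adjusted p = 0.568, 0 when adjusted over the list alone) were not called. The endothelium list was called lower without GRflox replicate 1 (0.0407), GRflox replicate 3 (0.0426) or corneaGRKO replicate 4 (0.0433), as were Slc4a11 without corneaGRKO replicate 1 (0.0283) and Aqp1 without GRflox replicate 4 (0.0259). The 16 Wnt pathway genes, with Dkk3 at -0.29, Wnt5a at -0.14 and Wnt10a at 0.12, had a positive median (0.01) but were put lower by camera (adjusted p = 0.865), and 2 were lower when adjusted over the list alone. Dkk3 passed without corneaGRKO replicate 1 (0.0207) and with the GC and length trend removed (0.0485), as did Wnt5a with the latter (0.0385). The 13 immediate early and stress genes, with Jun at 0.38, Atf3 at 0.32 and Egr1 at 0.63, were not called (camera adjusted p = 0.0981, 2 higher when adjusted over the list alone), nor were the 3 lacrimal and meibomian gland markers, Fabp5 at 0.25, Scd1 at 0.15 and Far2 at -0.01 (camera adjusted p = 0.276, 0 when adjusted over the list alone). The immediate early list was called higher without GRflox replicate 3 (0.033), corneaGRKO replicate 4 (0.0359) or corneaGRKO replicate 5 (0.0205), Jun without GRflox replicate 4 (0.0122) and Atf3 without corneaGRKO replicate 4 (0.0483). With library weights Aurka (0.0241), Cdc20 (0.0317), Per2 (0.0216), Slc4a11 (0.0177), Aqp1 (0.0151), Dsg3 (0.0145), Dkk3 (0.0147), Wnt5a (0.0488), Jun (0.00953) and Atf3 (0.033) passed. Skeletal muscle (Tnni2 -0.19, Atp2a1 0.02), red blood cell (Alas2 0.01) and adipose (Cidea 0.16) markers had fewer than 3 tested genes.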

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

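The tests with the macrophage, retina, pigment or conjunctival list as a covariate and the count of photoreceptor genes were chosen only after the results they concern were seen, as were the rim stroma list and leaving out corneaGRKO replicates 1 and 4 together, while the division of the libraries and the chromosome test were set beforehand. Of the 35 divisions of the 8 libraries into 4 and 4, 2 gave at least as many genes as the genotype (245), so chance cannot be excluded at the 0.05 level from the number of genes alone. The other division, GRflox replicates 1, 3 and 5 with corneaGRKO replicate 1 against the rest, gave 2338 genes, which points to a structure of the samples beyond genotype. It called 3 interferon-response genes, and the genotype called 13.

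All 19 interferon-response genes had positive differences in corneaGRKO, with 13 of 19 past the threshold and a median log2 difference of 0.55. Camera's call of the list was lost with an estimated correlation (adjusted p = 0.198). More macrophages in the pools would need the difference to shrink with the macrophage list as a covariate. The median was then 0.62 and all 19 stayed positive, but only 1 gene passed, because the median SE grew from 0.0811 to 0.151. With the pigment list, for iris or uvea, the median was 0.58 (median SE 0.1425, 1 past the threshold). With the conjunctival list the median was 0.68 (median SE 0.145, 6 past the threshold). None of these fits can decide, because the list means themselves parted the groups. The macrophage mean was up to 0.04 in GRflox and at least 0.11 in corneaGRKO, and the pigment mean up to 0.05 and at least 0.15. The conjunctival mean was up to 0.09 and at least 0.35. The slopes thus rest on the spread within groups. In corneaGRKO replicate 4 these means were highest and the interferon-response mean was lowest among the corneaGRKO libraries. Retina in the pools is argued against by a median of 0.60 with the retina list as a covariate (12 past the threshold). The retina mean parted the groups as well, but narrowly, at 0.07 in corneaGRKO replicate 5 against up to 0.03 in GRflox. It was highest in corneaGRKO replicate 4 (1.63), so the slope leans on that library. Changes local to a linked region are argued against by a largest share of 23.1% of the called genes on any chromosome. A linked region that held an upstream regulator was not tested and stays open, as do macrophages, iris or uvea, and conjunctival tissue in the pools. Receptor loss and Cre itself, which the design does not separate, stay open too. A response of the cornea to receptor loss may therefore be held only as a hypothesis among these.

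Krt8, Krt19 and Krt13 of the conjunctival list rose, and the list's median was 0.56. Retina in the pools as the whole source is argued against only weakly. With the retina list as a covariate the median was 0.37 and 2 genes passed, although the drop leaves room for a part. The retina mean also parted the groups narrowly and was highest in corneaGRKO replicate 4 (1.63), so the slope leans on that library. Iris or uvea stays open, since with the pigment list as a covariate the median was 0.0944 (median SE 0.118) and 0 genes passed, although melanocytes of a limbal rim would carry the same markers and the pigment mean itself parted the groups. More limbal or scleral rim could not be told apart from a change within the epithelium, because the 11 tested genes of the rim stroma list gave a camera p of 0.334, with 1 higher when adjusted over the list alone (Mgp, 0.33, over all genes adjusted p = 0.0831, or 0.0432 with library weights) and Comp at 0.70 (adjusted p = 0.168), and a rim of epithelium without stroma would not move that list. Receptor loss in the epithelium stays open, untested.

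Photoreceptor transcripts were unevenly spread, with 0 of 5 tested retina markers past the threshold. In corneaGRKO replicate 4, 11 of 12 listed photoreceptor genes lay above every GRflox library, with a median rise of 0.85 and Gnat1 at 8.21, which is consistent with retina carried into that pool. The same count was 11 in replicates 1 and 3, where the median rise was 0.17 and 0.06, and 6 in replicate 5. The test looked at replicate 4 because its values had been seen, several of these genes lie near the floor, and no biological explanation was tested.

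Dixon's ratio was computed in 320 groups of 4 libraries, and in 20 (6.25%) 1 library stood far from the others, where chance gives about 1 in 20. In 6 of the 20 this was corneaGRKO replicate 4, at 7.31 for Flt1, 8.97 for Col18a1, 14.02 for Dsg1a, 9.51 for Cldn1, 6.54 for Atf3 and 5.74 for Cidea. In corneaGRKO the others were Stfa1 at 7.51 in replicate 3, Dsg3 at 13.36 in replicate 1 and the corneal endothelium list mean at -0.12 in replicate 1. In GRflox replicate 1 they were Slc4a11 at 13.49 and Wnt10a at 10.08, and in GRflox replicate 3 Nyap1 at 10.58, Esr1 at 7.02 and Wnt5a at 12.02. In GRflox replicate 4 they were Aqp1 at 14.55, Dsg1a at 14.53, Dsg3 at 13.49 and Sesn2 at 9.15, and in GRflox replicate 5 Krt14 at 13.36 and Flt1 at 6.20.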

How the results depend on the processing

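Leaving out corneaGRKO replicates 1 and 4 together, removing the GC and length trend, and the within-group component as a covariate were chosen after the data were seen. In every alternative that tested them, the genes past the threshold with all libraries kept their sign (245, or all 199 still tested at a mean of 7 and 237 with GC and length values). The groups did not overlap in any of the 245. Leaving out or weighting libraries, the block, the filters and the pseudocount therefore could not have turned a sign, so the kept signs are no test there. Nr3c1 passed in each of the 8 fits without 1 library, from -0.52 to -0.43. Same-numbered libraries deviated with correlations of 0.51, -0.28, 0.26 and 0.06 for replicates 1, 3, 4 and 5, so the numbers do not pair all the libraries. The first component of the within-group deviations, with 45.8% of their variance, was -5.65 in GRflox and -10.16 in corneaGRKO for replicate 1. For replicate 4 it was 8.09 and 10.04, so a batch shared by these numbers is not excluded. For replicates 3 and 5 it was -2.81 and 1.37, and 0.37 and -1.26. The replicate block gave 663 genes, 466 higher, 197 lower and 8 of at least 1 on the log2 scale, 240 shared with the 245. Under that block 30 named genes passed that otherwise did not: Per1 (0.0188), Fkbp5 (0.0275), Krt4 (0.0307), Krt14 (0.0345), Krt15 (0.0422), Krt17 (0.0381), Tslp (0.0287), Tlr3 (0.0191), Col18a1 (0.0209), Angpt1 (0.0298), Slc4a11 (0.0164), Tnc (0.0149), Dkk3 (0.0256), Jun (0.0106), Atf3 (0.0268), Egr1 (0.0268), Dct (0.0278), S100b (0.0164), Sox10 (0.0336), Fmod (0.0224), Ogn (0.013), Mgp (0.0275) and the vessel genes Flt1 (0.0237), Emcn (0.0371), Vwf (0.0254), Mmrn1 (0.0076), Lyve1 (0.00654), Reln (0.0301), Rgs5 (0.0268) and Myh11 (0.0263), while H2-Ab1 (0.0519) no longer did. Library weights gave 1980 genes (973 higher, 1007 lower, 9 of at least 1), with 44 named genes newly past the threshold. The weights were estimated from the same 8 libraries, so these p-values may be too small. The within-group component gave 1364 (843, 521 and 8). That component was taken from the residuals of the same data, so its p-values are too small. Quantile normalization gave 202 genes, median centring 263, no filter 245, a mean of at least 7 195, the pseudocount 228, no trend 215 and robust moderation 259. Lower genes numbered 133 with the GC and length trend removed and 41 without corneaGRKO replicates 1 and 4 together. Without 1 library the count ran from 68 (GRflox replicate 5) to 574 (corneaGRKO replicate 1), with 52 to 416 higher, 16 to 158 lower and 4 to 10 of at least 1. Among lists, the estimated correlation ended all 15 calls, among them those of the interferon-response (adjusted p = 0.198), blood endothelium (0.432) and cytokine (0.435) lists; fry kept 2 of the 15 and ended, among others, those of blood endothelium (0.186) and cytokines (0.274), library weights those of cytokines (0.106) and retina (0.358), and a mean of at least 7 those of blood endothelium (0.185), innate sensing (0.0548) and nerve (0.051). Lists called that were otherwise not were corneal endothelium with no filter (0.0382) and with the GC and length trend removed (0.0367), proliferation with no filter (0.0345) and immediate early genes with the GC and length trend removed (0.0369). The epidermal keratinization list was called with no filter (0.0382), quantile normalization (0.0238), the GC and length trend removed (0.0441) and without corneaGRKO replicates 1 and 4 together (0.0232). Without 1 library its adjusted p ran from 0.0144 to 0.257, that of the cytokine list from 0.00296 to 0.123 and that of the stromal keratocyte list from 0.0396 to 0.643. Directions that turned were of uncalled results. The circadian list turned with fry (0.851), median centring (0.968), no filter (0.772) and without corneaGRKO replicates 1 and 4 together (0.741); the Wnt list at a mean of 7 (0.918), with no filter (0.967) and with quantile normalization (0.991); the corneal epithelium list at a mean of 7 (0.958), with quantile normalization (0.197) and without corneaGRKO replicates 1 and 4 together (0.741); the steroid list with no filter (0.909); and the epithelial junction list with quantile normalization (0.920). Without 1 library, adjusted p ran from 0.245 to 0.9996 for the circadian, 0.681 to 0.9996 for the corneal epithelium, 0.257 to 0.9996 for the steroid, 0.00352 to 0.9996 for the lens, 0.504 to 0.982 for the Wnt and 0.396 to 0.891 for the junction list. Pax6 was 0.0331 with library weights, 0.0303 with quantile normalization, 0.0548 without corneaGRKO replicates 1 and 4 together and -0.0349 to 0.0135 without 1 library; Far2 was 0.0133 with library weights and -0.0417 to 0.00359 without 1 library. Krt12, the highest gene of every library, was 0 with quantile normalization, which gives the first rank 1 value in every library and so tests nothing there. Agr2 was -0.00359 with quantile normalization, -0.0156 without corneaGRKO replicates 1 and 4 together and -0.0125 to 0.0457 without 1 library. Alas2 was -0.0169 and Atp2a1 -0.0165 with quantile normalization, and without 1 library Alas2 ran from -0.0244 to 0.0306, Atp2a1 from -0.0172 to 0.0460 and Kit from -0.0215 to 0.0596. The cause was not tested, except that leaving out libraries lowers their number. Of 585 list and 2611 single-gene values under the alternatives, 501 and 2287 kept their direction and side of the threshold. Robust moderation has no form for camera, and the count test was not run, as whole reads could not be recovered.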

Other observations

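The lists of this part, the test without B2m, Nlrc5 and Tap1, the removal of the GC and length trend and its test on the divisions of the libraries were chosen only after the data were seen. Some genes of MHC class I antigen processing rose in corneaGRKO. B2m, the light chain of MHC class I, rose by 0.50 (SE 0.0463, limma adjusted p = 0.00124, n = 4 per group), Nlrc5, the transactivator of class I genes, by 0.28 and the peptide transporter Tap1 by 0.23. All 12 tested genes of the list had positive differences, 3 passed over all genes and 4 when adjusted over the list alone. Tap1 missed the threshold without GRflox replicate 1 (adjusted p = 0.0762), 3 (0.0904), 4 (0.0643) or 5 (0.144), without corneaGRKO replicate 3 (0.117), 4 (0.0605) or 5 (0.0725), with no filter (0.0563) and with no trend (0.0503). Camera gave the list a p of 4.46e-07, or 0.089 with an estimated correlation, but B2m, Nlrc5 and Tap1 had been seen to be higher. Without them, the hypothesis that other genes of the list are higher as well was met by camera (p = 0.00231), but not with an estimated correlation (p = 0.265). Of these 9 genes 0 passed over all genes or when adjusted over the 9 alone, while H2-D1 passed when adjusted over all 12 (limma adjusted p = 0.0349). Whether the list moves with the interferon-response genes was not tested. Tap1 lies on chromosome 17, as do H2-Aa and H2-Ab1, and changes local to a linked region were not tested for this list.

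A second hypothesis, that other amino-acid response genes fell along with Slc7a5 and Mthfd2, stays undecided. Mthfd2 itself missed the threshold without GRflox replicate 1 (adjusted p = 0.0518), 3 (0.0517) or 5 (0.0746). The 15 other genes had a median difference of -0.04 and a camera p of 0.159, with 5 positive, 0 past the threshold over all genes, and, adjusted over the list alone, 3 lower (Asns, Slc7a3 and Atf5) and 1 higher (Sesn2). Asns, asparagine synthetase, was the nearest to passing, at -0.37 (limma adjusted p = 0.0784), and passed without corneaGRKO replicate 5 (0.0428), while with library weights Asns (0.0346), Slc7a3 (0.0273), Atf5 (0.0177) and Sesn2 (0.011) all passed.

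The division of the libraries with 2338 genes raised the question whether GC content and transcript length differ between libraries. Across genes, which are not independent replicates, the genotype difference had a Spearman correlation of 0.25 with log2 transcript length and -0.15 with GC content. Among the 12815 genes with both values (96.6% of those tested), the highest count of another division was 2350, and it was 1338 (56.9%) after the trend was removed from each library. Which division gave each highest count was not recorded, and the trend may not have been removed in full. The trend may thus be a part of that structure, and whether it is the whole source stays undecided. The genotype gave 230 genes before and 336 after, with 13 interferon-response genes past the threshold after. The first principal component of the 8 libraries held 52.0% of the variance, with corneaGRKO replicate 4 at 16.5 and GRflox replicate 1 at -10.00.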
